A study of Mus musculus with 3 samples.

How the data were processed

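RNA was measured in 3 colonic myeloid populations of healthy BALB/c mice, with 1 library each of CD64- dendritic cells (DC), CD64+ macrophages and Gr-1+ CD11b+ cells. Total RNA was extracted with the RNeasy kit, full-length cDNA was made with SMART-Seq HT and libraries were prepared with Nextera, per the labels' protocols. The authors deposited 1 table per library with an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each gene symbol. TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1 and the mouse build mm10 are listed per the submitters' processing notes, with no role or order. The gene annotation, the filters and whether RNA of several mice was pooled were not given in the sources used here.

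FPKM divides by length and by library total, so a few very abundant transcripts lower all other values of a library. The 10 highest genes held 15.0% of the FPKM sum in DC, 22.2% in macrophages and 33.5% in Gr-1+ CD11b+ cells. The sums differed, as did the number of genes at 1 FPKM or more, which was 11810, 13047 and 16004. No source used here states that the libraries were stranded, so overlapping and antisense genes cannot be told apart. Genes with near-identical copies can be listed near 0 when fragments are assigned to the other copy. An exact 0 was reported only as listed at 0.

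Depth was estimated from the values. For genes with a single annotated transcript longer than 800 nt, FPKM times length stepped in multiples of what 1 fragment was worth. On a transcript of 1 kb, 1 fragment corresponded to 0.128 FPKM in DC, 0.172 in macrophages and 0.445 in Gr-1+ CD11b+ cells. Of the low values used, 75.4%, 71.4% and 71.2% lay within 0.2 of a whole multiple, where 40% would by chance. The depths relative to the Gr-1+ CD11b+ library were thus 3.48, 2.59 and 1. A value resting on 3 fragments of a 1 kb transcript was 0.384, 0.516 and 1.34 FPKM. Amplified fragments without molecular identifiers are not independent molecules, so this covers counting error only.

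Values were used as deposited. A pseudocount of 1 was added before taking log2. Of 24346 symbols, 23310 were found in GENCODE M21 (GRCm38, the build called mm10 elsewhere), which gave coordinates and transcript lengths. No symbol occurred more than once. Genes with 1 FPKM or more in any library, 17329 in number, were compared. With 1 library per population no test was possible. A gene was called higher in a library by a size rule fixed before the data were examined, a log2 difference of 2 or more and an FPKM of 10 or more in the higher library. For each list of 3 or more expressed genes, the percentile of its median difference was taken among 10000 random lists of the same size, matched in 20 bins of mean expression. These percentiles describe the libraries and are not tests. The lists were 37 sets holding 602 genes, 586 of them in the tables, fixed before the data were examined.

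The genes named in the text followed a rule fixed at the same time. It took all purinergic genes and sort markers, the 12 genes with the largest difference per comparison and direction and per population, and 4 members of each other list with the highest FPKM and 4 with the largest difference. Immunoglobulin and T cell receptor segments and symbols that are only codes were counted and not named. A few genes that the rule would name are not reported here.

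The size rule was tested on simulated fragment counts at the 3 depths, over 23310 genes. For DC against macrophages and for Gr-1+ CD11b+ cells against DC it called 50 of 50 genes raised 8-fold and 50 of 50 lowered 8-fold, and for Gr-1+ CD11b+ cells against macrophages 50 and 49. It called 0 of 100 genes changed 2-fold in each comparison, and 1, 1 and 0 of 23110 unchanged genes. The changed genes were drawn only from genes whose mean level lay well above the floor of 10 FPKM, so levels just above it were not tried. The 2 fold changes lay on either side of the log2 limit. These calls thus show only that counting error rarely undid the rule at such levels. Variation between mice or preparations and differences in background between the libraries were not simulated. Of 200 random lists, 7% lay outside the central 95% of percentiles, and a list shifted by 2 reached percentile 100.

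The alternatives were pseudocounts of 0.1 and 10, no expression floor beyond 1 FPKM or a floor of 30 FPKM, log2 limits of 1 and 3, and 3 scalings (equal sums, median ratios and equal 75th percentiles). Another 3 were added after the data were seen: subtracting the median of 1452 olfactory and vomeronasal receptor genes, leaving out 1334 symbols whose longest transcript was under 300 nt, and leaving out the B and plasma cell list. Counts of list members past the size rule under the 3 scalings were also added then. The calculations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.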

Results

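Gene expression was measured by RNA sequencing in 3 populations of colonic myeloid cells from untreated, healthy mice of the BALB/c strain. They were CD64- dendritic cells (DC), CD64+ macrophages and Gr-1+ CD11b+ cells, which the labels describe as neutrophils and monocytes. CD64 is the high-affinity IgG receptor encoded by Fcgr1, CD11b is the integrin encoded by Itgam, and Gr-1 is a surface epitope of the Ly6 proteins of granulocytes and monocytes. The series title concerns E-NTPD8, an enzyme that hydrolyses extracellular ATP, and metabolism that depends on the ATP-gated channel P2X4. Each population was represented by 1 library, so no difference between populations has a replicate check, and no test or p-value is given. All values are FPKM, and differences are on the log2(FPKM + 1) scale, which understates the differences of genes with low values.

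The libraries listed the same 24346 gene symbols, of which 17329 reached an FPKM of 1 or more in at least 1 library. FPKM steps of genes with a single transcript gave the DC and macrophage libraries 3.48 and 2.59 times the depth of the Gr-1+ CD11b+ library. The level of genes that colonic myeloid cells should not use also differed. Over 1452 olfactory and vomeronasal receptor genes, the 95th percentile was 0.611 FPKM in DC, 3.24 in macrophages and 9.69 in Gr-1+ CD11b+ cells. These 3 values are called the silent-gene level below, a measure chosen after the values were seen. Lower values are not read as expression.

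**Figure D1:**
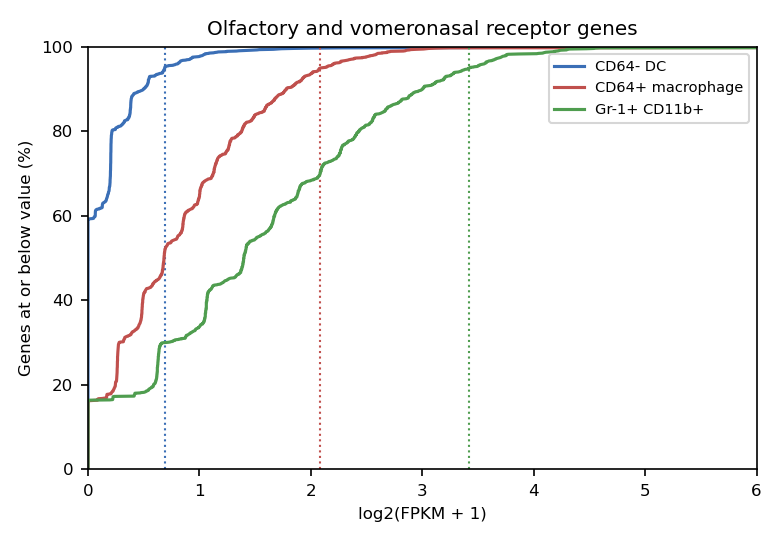
Cumulative share (percent) of 1452 olfactory and vomeronasal receptor genes at or below each value of log2(FPKM + 1), 1 line per library, with the x axis ending at 6. Dotted lines mark the 95th percentiles, at 0.611, 3.24 and 9.69 FPKM in the DC, macrophage and Gr-1+ CD11b+ libraries.

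Transcripts of the sort markers followed the gates for CD64 and CD11b. Fcgr1 was at 113 FPKM in macrophages, 9.23 in DC and 12.3 in Gr-1+ CD11b+ cells. Itgam was at 172 FPKM in Gr-1+ CD11b+ cells, 114 in macrophages and 18.7 in DC. Ly6c2, which encodes a Ly6C protein of monocytes, was at 878, 782 and 320 FPKM in DC, macrophages and Gr-1+ CD11b+ cells, and Ly6c1 was at 68.8, 44.0 and 79.9. Itgax, the gene of CD11c, was at 19.7, 47.0 and 16.4 FPKM in the same order, and the pan-leukocyte gene Ptprc was at 147, 206 and 204. Ly6g was not analysed here.

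The first question, raised by the series title, was which receptors and enzymes of extracellular ATP and adenosine each population expressed. P2rx4, which encodes P2X4, was detected in all 3 libraries, at 203 FPKM in macrophages, 73.4 in DC and 25.9 in Gr-1+ CD11b+ cells. It was lower in Gr-1+ CD11b+ cells than in macrophages by the size rule (a log2 difference of 2 or more, with 10 FPKM or more in the higher library), with a difference of -2.92. The differences of -1.45 between DC and macrophages and -1.47 between Gr-1+ CD11b+ cells and DC did not reach that size. Macrophage RNA carried into the DC and Gr-1+ CD11b+ libraries, an open hypothesis treated at the end, may give part of their P2rx4 values. Entpd8, which encodes E-NTPD8, was at 1.21 FPKM in DC, 0.487 in macrophages and 1.13 in Gr-1+ CD11b+ cells, and both latter values lay below the silent-gene level of their library. The DC value exceeded the lower level of its library, 0.611 FPKM, but was close to that of Gr-1+ CD11b+ cells. These low values do not single out DC. P2rx4 lies on chromosome 5 at positions 122707544 to 122729738 on the plus strand and Entpd8 on chromosome 2 at 25080304 to 25085716 on the plus strand (GRCm38), and both are annotated as protein-coding genes.

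P2rx7, the gene of the ATP receptor that can activate the NLRP3 inflammasome, was at 31.9 FPKM in macrophages, 7.21 in DC and 5.54 in Gr-1+ CD11b+ cells. It was higher in macrophages than in both other libraries by the size rule. With each library scaled to the same sum, its difference from DC was -1.65 and no longer reached the rule, and with median-ratio scaling its difference between Gr-1+ CD11b+ cells and macrophages was -1.82. Of the remaining P2X genes, P2rx1 was at 3.46 FPKM in DC, 3.79 in macrophages and 0.531 in Gr-1+ CD11b+ cells. P2rx2, P2rx3, P2rx5 and P2rx6 did not exceed the silent-gene level in any library.

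Among the P2Y receptors, G protein-coupled receptors most of which bind nucleotides, 4 of 8 were higher in macrophages than in DC by the size rule and 1 was lower. With equal sums 3 were higher, as P2ry2 no longer passed. P2ry6, a UDP receptor, was at 58.8 FPKM in macrophages against 7.50 in DC and 9.95 in Gr-1+ CD11b+ cells, and P2ry12 was at 11.3 against 0.933 and 3.34. P2ry2, an ATP and UTP receptor, was at 29.4 FPKM in Gr-1+ CD11b+ cells, 12.1 in macrophages and 1.78 in DC. P2ry13, an ADP receptor, was at 50.8, 37.0 and 4.29 in the same order. P2ry10, whose receptor binds lysophosphatidylserine, was the reverse, at 123 FPKM in DC, 12.6 in macrophages and 4.22 in Gr-1+ CD11b+ cells. The DC library also held B and plasma cell genes, described below, and whether P2ry10 came from such cells was not tested. P2ry14 was at 12.2, 25.2 and 8.92 FPKM in DC, macrophages and Gr-1+ CD11b+ cells. P2ry1 exceeded the silent-gene level only in DC, at 0.646 FPKM, and P2ry4 in no library.

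Adora2b, the low-affinity adenosine receptor gene, was at 215 FPKM in macrophages, 23.6 in DC and 29.5 in Gr-1+ CD11b+ cells, and was higher in macrophages than in both others by the size rule. Adora2a was at 15.3, 7.46 and 3.13 FPKM in the same order. As with P2rx4, carried-over macrophage RNA may give part of the Adora2b values in DC and Gr-1+ CD11b+ cells. Entpd1, which encodes the ATP- and ADP-hydrolysing enzyme CD39, was at 295 FPKM in Gr-1+ CD11b+ cells, 83.2 in macrophages and 25.1 in DC. Its difference between Gr-1+ CD11b+ cells and DC reached the size rule. The difference of 1.82 from macrophages did not, although it was 2.39 with median-ratio scaling. Entpd3, a related ATP-hydrolysing enzyme, was at 33.0 FPKM in Gr-1+ CD11b+ cells and below the silent-gene level in DC and macrophages, at 0.374 and 1.48. Nt5e, the gene of the AMP-hydrolysing enzyme CD73, was at 14.99 FPKM in Gr-1+ CD11b+ cells, 7.75 in DC and 2.03 in macrophages. Cd38, an NAD-consuming ectoenzyme gene, was at 80.6, 123 and 19.6 FPKM in DC, macrophages and Gr-1+ CD11b+ cells. Ada, the adenosine deaminase gene, was at 22.5, 5.09 and 2.12. Entpd4 was listed at 0 in every library, which can be a failed estimate.

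Of 35 P2X, P2Y, adenosine receptor and ectoenzyme genes, 25 exceeded the silent-gene level in DC, 19 in macrophages and 10 in Gr-1+ CD11b+ cells. That level was 0.611, 3.24 and 9.69 FPKM in the same order, so these counts do not rank the populations by expression. The values of P2rx1, P2rx7, P2ry10, P2ry12, P2ry14, Adora2a and Ada in Gr-1+ CD11b+ cells, and of Nt5e in macrophages, were at or below it. Among the ATP release and nucleoside transport genes, the channel gene Panx1 was at 30.6, 18.5 and 6.99 FPKM in DC, macrophages and Gr-1+ CD11b+ cells. The nucleoside transporter gene Slc29a1 was at 21.2, 49.5 and 15.8. Of 9 such genes at 1 FPKM or more, 1 passed the size rule in any comparison, Slc29a3, at 22.9 FPKM in macrophages and 3.29 in Gr-1+ CD11b+ cells. It did not pass with median-ratio or 75th percentile scaling, and with equal sums Panx1 and the vesicular ATP transporter gene Slc17a9 were higher in DC than in Gr-1+ CD11b+ cells, and Slc17a9 than in macrophages.

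**Figure D2:**
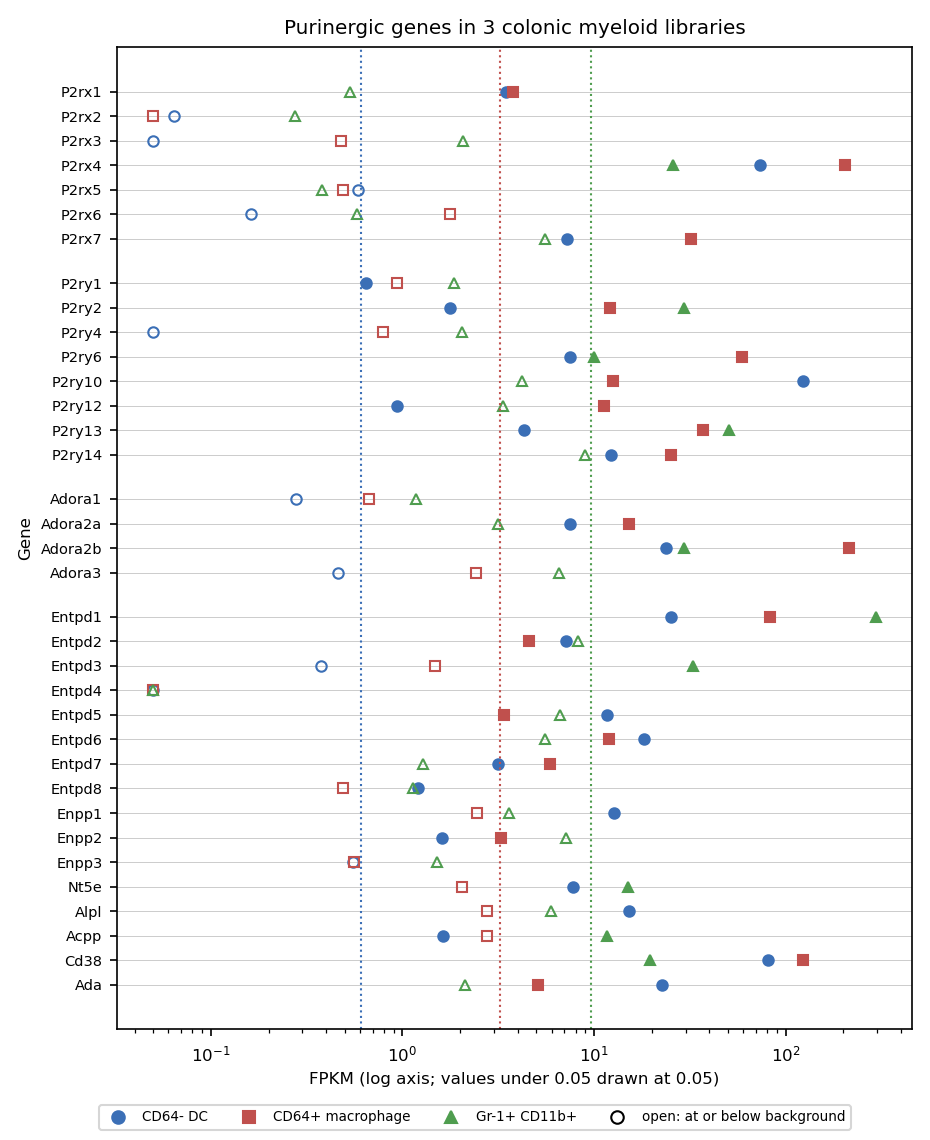
FPKM (log axis) of 35 purinergic genes in the DC library (circles), the macrophage library (squares) and the Gr-1+ CD11b+ library (triangles), with values under 0.05 drawn at 0.05. Dotted lines mark the silent-gene level of each library, and open symbols lie at or below it; P2rx4 was highest in macrophages at 203 FPKM and Entpd1 in Gr-1+ CD11b+ cells at 295 FPKM.

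CD64- DC and CD64+ macrophages were compared to ask how these antigen-presenting populations of the colon differ. Macrophage marker genes were higher in the CD64+ library. Of 27 macrophage marker genes, 21 were higher in macrophages than in DC by the size rule, with a median difference of -3.00 (DC minus macrophage), at the lower end of 10000 random lists of equal size and expression (percentile 0). Apoe, which encodes a lipid carrier, was at 19321 FPKM in macrophages and 2446 in DC. The complement genes C1qb and C1qc were at 4403 and 2212 FPKM in macrophages against 393 and 225 in DC. Cd14, a co-receptor gene for lipopolysaccharide, was at 5981 against 462.

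Of 30 cytokine and chemokine genes, 19 were higher in macrophages and 0 in DC by the size rule (median -2.17, percentile 0), and 12 and 1 with equal sums. Il23a, a subunit of interleukin-23, was at 132 FPKM in macrophages and 6.93 in DC, Tnf at 218 and 20.4, and Osm at 346 and 34.5. Of 18 inflammasome and interleukin-1 genes, 5 were higher in macrophages (median -1.16, percentile 0.03), including Il1b at 11637 against 1894 FPKM, Il1a at 813 against 73.4 and the receptor antagonist gene Il1rn at 1475 against 126. Of 23 pattern recognition receptor genes, 8 were higher in macrophages (median -1.49, percentile 0), including the C-type lectin gene Clec4e at 851 against 62.8 and Tlr2 at 332 against 30.3. Of 20 monocyte genes, 8 were higher in macrophages (median -1.46, percentile 0). Chil3 was at 566 against 28.8 FPKM, and Ccr2, a chemokine receptor of monocytes, at 247 against 27.6. Neutrophil markers moved with them, with 10 of 24 higher in macrophages than in DC (median -1.62, percentile 0), and 6 with equal sums.

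The DC library held higher transcripts of dendritic cell genes and of B cell genes. Of 24 dendritic cell markers, 7 were higher in DC than in macrophages by the size rule and 0 were lower (median 1.27, percentile 100). Ccr7, which directs migration to lymph nodes, was at 1004 FPKM in DC and 107 in macrophages, and Flt3, a growth factor receptor of dendritic cells, at 39.9 and 5.42. All 13 B and plasma cell genes measured were higher in DC (median 4.16, percentile 100), among them Jchain, which joins secreted antibody units, at 18847 against 982 FPKM, and Cd79a at 1489 against 59.3. Among the genes with the largest differences towards DC, Cd79a, Fcmr, Pou2af1 and Mzb1 belong to that list. Genes outside it were Fcrla, Cxcr5, Ly6d, Fcer2a, Ccr10, Dusp4 and Spib. Fcrla was at 163 FPKM in DC and 4.83 in macrophages, and Cxcr5, a receptor of follicular B cells, at 168 and 5.70.

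Genes of MHC class II presentation split between these libraries. The abundant genes Cd74 and H2-Ab1 were at 21523 and 16331 FPKM in DC and 30833 and 29149 in macrophages, without passing the size rule. H2-Ob, H2-Eb2, H2-DMb2 and H2-Oa were higher in DC by the rule, with H2-Ob at 227 against 17.7 FPKM and H2-Oa at 271 against 41.7. H2-Ob and H2-Oa encode an inhibitor of peptide loading that is used by B cells. Of 36 respiratory chain and ATP synthase genes, 0 passed the rule in either direction. In glycolysis, 3 of 25 genes passed it, all towards macrophages (median -0.65, percentile 0.48), among them the lactate exporter gene Slc16a3 at 218 against 35.8 FPKM and the hexokinase gene Hk3 at 71.0 against 9.66.

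In all, 266 genes were higher in DC and 401 in macrophages, and the libraries correlated across genes at a Pearson r of 0.90, where genes are not independent replicates. With each library scaled to the same sum, a shift of 0.39 towards DC, the counts were 416 and 264, so which population had more such genes turned with the scaling.

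**Figure D3:**
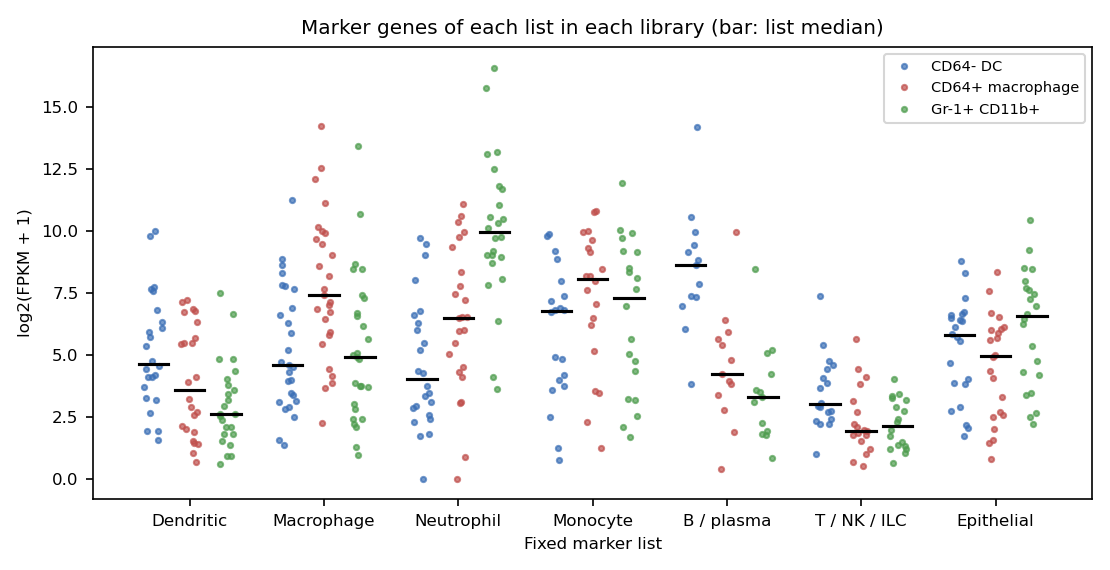
log2(FPKM + 1) of the genes of 7 marker lists fixed in advance, in the DC, macrophage and Gr-1+ CD11b+ libraries, with 1 point per gene at 1 FPKM or more in any library and a bar at each list's median. Median FPKM of the B and plasma cell list was 391 in DC, 17.6 in macrophages and 8.77 in Gr-1+ CD11b+ cells, and that of the neutrophil list was 15.2, 89.4 and 993.

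Gr-1+ CD11b+ cells were compared with DC to describe the granulocyte and monocyte population against the CD64- one. Neutrophil markers were higher in Gr-1+ CD11b+ cells. All 24 neutrophil markers at 1 FPKM or more in any library were higher in Gr-1+ CD11b+ cells by the size rule, with a median difference of 5.84 (percentile 100), and all 24 passed under each scaling. S100a8 and S100a9, the subunits of calprotectin, were at 98580 and 54906 FPKM in Gr-1+ CD11b+ cells against 828 and 521 in DC. Retnlg was at 9198 against 255 FPKM, G0s2, an inhibitor of lipolysis, at 8790 against 95.7, and Hdc, the enzyme gene for histamine synthesis, at 3310 against 35.2. Lcn2, an iron-sequestering antibacterial protein gene, was at 3579 against 43.1, and Csf3r, the receptor gene for G-CSF, at 838 against 9.85. Of 20 monocyte genes, 6 were higher than in DC by the size rule and 0 lower (median 0.18, percentile 95.2). With equal sums 6 were higher and 2 lower (median -0.18).

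Towards Gr-1+ CD11b+ cells over DC, the size rule was passed by 10 of 23 pattern recognition genes (median 1.11, percentile 99.98), 10 of 30 cytokine and chemokine genes (median 0.48, percentile 99.99) and 5 of 18 inflammasome genes (median 1.07, percentile 99.96). The cytokine median was 0.13 with equal sums and 1.20 with median-ratio scaling, and the genes past the rule were 8 and 11. With equal sums 7 pattern recognition and 4 inflammasome genes passed. Cxcl2 and Cxcl3, chemokines that attract neutrophils, were at 2110 and 605 FPKM in Gr-1+ CD11b+ cells against 107 and 12.7 in DC. Il1b was at 13362 against 1894 FPKM and Nlrp3, the inflammasome sensor gene, at 134 against 10.5. Within the cytokine list, 2 genes passed the rule in the opposite direction.

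DC had higher transcripts of antigen presentation genes. All 11 MHC class II genes were lower in Gr-1+ CD11b+ cells by the size rule (median -2.81, percentile 0), with Cd74 at 3010 against 21523 FPKM and H2-Aa at 1183 against 8296, and 6 were with median-ratio scaling. Of 24 dendritic cell markers, 13 were lower in Gr-1+ CD11b+ cells (median -2.09, percentile 0), and 7 with median-ratio scaling, with Ccr7 at 27.5 against 1004 FPKM. All 13 B and plasma cell genes were lower (median -5.56, percentile 0), with Jchain at 352 FPKM and Cd79a at 35.8. Of 34 ribosomal protein genes, 26 were lower by the rule (median -2.33, percentile 0), with Rps18 at 402 against 2661 FPKM. Only 1 of them was with median-ratio scaling (median -1.56) or with 75th percentile scaling (median -1.57), so most of these calls rested on the scaling. Among the 12 genes with the largest differences towards DC, Scarna8, H2-Q8 and Hbb-bs were at 0, 0.00176 and 0.0173 FPKM in Gr-1+ CD11b+ cells. These 3 have near-identical or overlapping copies and their values are uncertain.

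Glycolysis and respiratory chain genes had medians of opposite sign between Gr-1+ CD11b+ cells and DC. In glycolysis, 5 of 25 genes were higher in Gr-1+ CD11b+ cells by the size rule and 0 were lower (median 0.72, percentile 99.96). Slc16a3 was at 1572 against 35.8 FPKM, the glucose transporter gene Slc2a3 at 222 against 8.67, Pfkfb4, which controls glycolytic flux, at 55.8 against 5.004, and Hk3 at 78.4 against 9.66. The median of 36 respiratory chain and ATP synthase genes was -1.21 (percentile 0.78), close to the -1.17 of 15 housekeeping genes, and Ndufa4, a component of the chain, passed the rule at 136 against 635 FPKM, as 3 genes of the list did with equal sums. Irg1, which makes itaconate from a tricarboxylic acid cycle intermediate, was at 3952 against 59.4 FPKM. The median of the 24 cycle genes was -0.93 (percentile 28.2), with Idh2 at 19.3 against 96.0 FPKM and Mdh1 at 35.3 against 156. In the pentose phosphate pathway, Pgd was higher at 149 against 33.9 FPKM, whereas Pgls was lower at 29.5 against 163. Of 17 fatty acid oxidation genes, 0 passed the rule. With 75th percentile scaling the medians were 1.49 for glycolysis, with 8 genes higher by the rule, -0.44 for the respiratory chain, -0.18 for the cycle and -0.41 for housekeeping genes. Of these lists 0 genes were then lower by the rule, and Ndufa4, Idh2, Mdh1 and Pgls no longer passed it. With equal sums Pgd no longer passed, 5 cycle genes were lower in place of 2, and the glycolysis median was 0.36 with 4 genes higher.

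In all, 633 genes were higher in Gr-1+ CD11b+ cells and 1088 in DC, with a Pearson r of 0.74 across genes. Scaling by median ratios, a shift of 0.78 towards Gr-1+ CD11b+ cells, gave 1126 and 353, and scaling to the same 75th percentile gave 1141 and 370, so the larger count turned with the scaling.

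Gr-1+ CD11b+ cells and macrophages were compared to separate the granulocyte and monocyte population from the CD64+ one. Of 24 neutrophil markers, 20 were higher in Gr-1+ CD11b+ cells by the size rule (median 3.76, percentile 100), led by Ngp, a granule protein gene, at 413 against 7.23 FPKM, with S100a8 at 98580 against 2154 and Lcn2 at 3579 against 91.0. Other genes with large differences were Asprv1, at 355 against 6.08 FPKM, and Prok2, at 86.7 against 1.68. Of 27 macrophage markers, 18 were lower in Gr-1+ CD11b+ cells (median -3.10, percentile 0). C1qc was at 169 against 2212 FPKM, and Trem2, a lipid-sensing receptor gene, at 5.92 against 86.3. Cd14 was the exception among the abundant members, at 10998 FPKM in Gr-1+ CD11b+ cells and 5981 in macrophages. Retnla was at 53.4 FPKM in Gr-1+ CD11b+ cells and 1899 in macrophages.

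Monocyte genes went both ways, with 2 of 20 higher and 4 lower in Gr-1+ CD11b+ cells than in macrophages by the size rule (median -0.74, percentile 41.5). With median-ratio scaling 3 were higher and 3 lower (median -0.20). Ccr2 was at 25.8 FPKM against 247 and Ms4a4c at 31.3 against 292. Of 11 MHC class II genes, 10 were lower in Gr-1+ CD11b+ cells (median -3.36, percentile 0), and 8 with median-ratio scaling. Of 11 costimulatory genes, 5 were lower (median -0.45, percentile 56.6), and 4 with that scaling (median 0.014). Among them Cd83 was at 155 against 1684 FPKM and Cd86 at 22.2 against 242. Of 30 cytokine and chemokine genes, 9 were lower and 2 higher (median -1.28, percentile 1.09). The chemokine genes Cxcl16 and Ccl5 were at 44.5 and 71.0 FPKM against 554 and 634, and Cxcl3 was at 605 against 58.7.

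In glycolysis, Slc2a3 at 222 against 6.30 FPKM and Slc16a3 at 1572 against 218 were higher in Gr-1+ CD11b+ cells than in macrophages by the size rule. The median of the 25 genes was -0.12 (percentile 98.0), and it was 0.45 with median-ratio scaling and 0.46 with 75th percentile scaling, so its sign depended on the scaling. Irg1 was at 3952 against 439 FPKM. The medians of the respiratory chain and ATP synthase genes and of the ribosomal protein genes were -1.18 (percentile 4.92) and -1.66 (percentile 0), with 0 genes of either list passing the size rule. With median-ratio scaling they were -0.61 and -1.08. The median of 15 housekeeping genes was -0.94 against macrophages and -1.17 against DC.

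In all, 244 genes were higher in Gr-1+ CD11b+ cells and 591 in macrophages, with a Pearson r of 0.84 across genes. Scaling by median ratios, a shift of 0.58 towards Gr-1+ CD11b+ cells, gave 618 and 251, and scaling to the same 75th percentile gave 647 and 244, so the larger count turned here too.

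**Figure D4:**
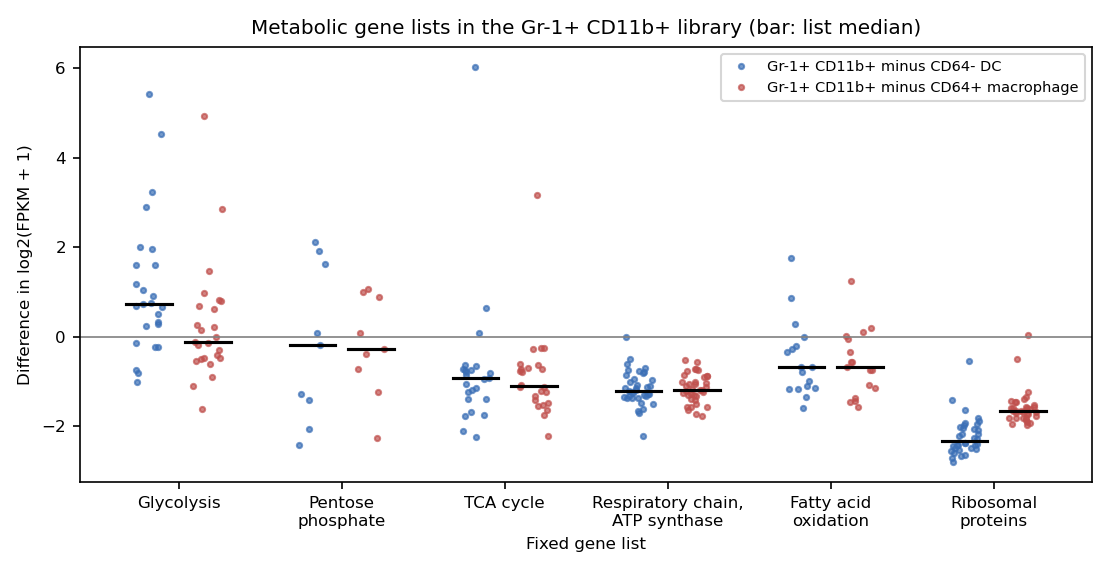
Differences in log2(FPKM + 1) of the genes of 5 metabolic lists and the ribosomal protein list, Gr-1+ CD11b+ minus DC and Gr-1+ CD11b+ minus macrophage, with 1 point per gene at 1 FPKM or more in any library and a bar at each list's median. The glycolysis medians were 0.72 and -0.12 (1.49 and 0.46 with 75th percentile scaling), and those of the respiratory chain and ATP synthase were -1.21 and -1.18 (-0.44 and -0.59).

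Against both other libraries at once, 210 genes passed the size rule in DC, 149 in macrophages and 194 in Gr-1+ CD11b+ cells. The macrophage set included 16 of 27 macrophage markers and the Gr-1+ CD11b+ set 20 of 24 neutrophil markers. The DC set included all 13 B and plasma cell genes and 5 of 24 dendritic cell markers, and 12 and 3 with median-ratio scaling. The leading macrophage genes included Mmp13, a collagenase gene, at 83.3 FPKM against 4.47 in DC and 4.48 in Gr-1+ CD11b+ cells, and Aoah, which inactivates lipopolysaccharide, at 84.5 against 6.47 and 4.29.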

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

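The median subtraction and the omission of short transcripts or of B and plasma cell genes were chosen after the data were seen; the other settings were planned. Counts by the size rule are given here as DC over macrophages, macrophages over DC, Gr-1+ CD11b+ over DC, DC over Gr-1+ CD11b+, Gr-1+ CD11b+ over macrophages and macrophages over Gr-1+ CD11b+, where the values as deposited gave 266, 401, 633, 1088, 244 and 591. A pseudocount of 10 gave 101, 185, 293, 309, 110 and 219, and the genes enriched in DC, macrophages and Gr-1+ CD11b+ cells were then 87, 73 and 93 in place of 210, 149 and 194. A log2 limit of 1 gave 969, 986, 1045, 3226, 818 and 2610, with 808, 506 and 649 enriched. A limit of 3 gave 118, 113, 359, 240, 100 and 124, with 94, 35 and 84 enriched. These follow from the construction of the rule. Without a floor beyond 1 FPKM, 1748 genes were higher in Gr-1+ CD11b+ cells than in DC, 395 than in macrophages and 306 than in both. A floor of 30 FPKM gave 146 genes for DC over macrophages, 377 and 666 for Gr-1+ CD11b+ over DC and the reverse, 158 for Gr-1+ CD11b+ over macrophages, and 125 and 129 enriched in DC and Gr-1+ CD11b+ cells. With equal sums, 416 genes were higher in DC than in macrophages and 264 lower, 1814 were higher in DC than in Gr-1+ CD11b+ cells and 326 were enriched in DC. Median-ratio scaling gave 1126 genes for Gr-1+ CD11b+ over DC, 353 for the reverse, 618 for Gr-1+ CD11b+ over macrophages, 251 for the reverse and 499 enriched in Gr-1+ CD11b+ cells. Equal 75th percentiles gave 1141, 370, 647, 244 and 522 for the same counts. The cause of these moves was not tested. With the silent-gene median subtracted, 1665 genes were higher in DC and 911 in macrophages than in Gr-1+ CD11b+ cells. All other counts stayed within 1.5 times the deposited ones. Leaving out the B and plasma cell list could remove only its own members, so it does not show the counts without other B cell genes. No symbol occurred more than once, so keeping the highest entry per symbol gave no separate values. Each list median was counted once per setting under the pseudocounts and scalings. Of these values 452 moved by at most 1.5-fold and 101 by more, with the 2 named next counted apart. Counted once per median, 28 of 111 medians changed sign in at least 1 of these settings. For lists whose percentile as deposited lay outside the central 95%, 2 values changed sign: glycolysis between Gr-1+ CD11b+ cells and macrophages, -0.12 as deposited, was 0.45 with median-ratio scaling and 0.46 with equal 75th percentiles; the cause was not tested. Single-gene differences, also counted once per setting, stayed within that margin in 1297 cases and did not in 413. Depth limits low values most in the Gr-1+ CD11b+ library, where 3 fragments on a 1 kb transcript gave 1.34 FPKM against 0.384 in DC.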

Other observations

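Markers of cells outside the sorted myeloid populations were present in every library. Epithelial genes had a median of 53.8 FPKM in DC, 29.9 in macrophages and 93.3 in Gr-1+ CD11b+ cells, with the antimicrobial lectin gene Reg3b at 440, 324 and 1376 and Krt8, a keratin of simple epithelia, at 156, 101 and 361. The epithelial median was 1.58 higher in Gr-1+ CD11b+ cells than in macrophages on the log2 scale (percentile 100), where 3 of 22 genes passed the size rule, and 13 with median-ratio scaling. Of 18 T, NK and innate lymphoid genes, 2 were higher in DC than in macrophages by the size rule and 4 with equal sums (median 1.03, percentile 100 as deposited), Cd2 at 163 against 20.7 FPKM and Lck, a T cell receptor kinase gene, at 40.6 against 5.36. Stromal genes had a median difference of 0.70 between DC and macrophages (percentile 99.8), with 0 of 13 past the rule and Col3a1 at 75.6 against 27.7. Of 12 eosinophil genes, 2 were higher in macrophages than in DC by the size rule (0 with equal sums) and 1 in DC, the granule protein gene Prg2 at 108 against 6.31 FPKM (list median -0.93, percentile 0.36). The Y-linked gene Ddx3y was at 26.4, 25.7 and 20.7 FPKM and Xist at 0.0124, 0.206 and 0.491.

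Of 18 interferon-response genes, 3 were lower in DC than in macrophages by the size rule and 2 with equal sums (median -1.06, percentile 0.02 as deposited), among the former Isg15 at 65.5 against 366 FPKM. In Gr-1+ CD11b+ cells, 4 of 18 were higher than in DC and 1 with equal sums (median 0.88, percentile 99.97 as deposited), among the 4 Oasl2 at 141 against 20.2. Cell-cycle genes had a median of 1.13 between DC and macrophages (percentile 100), with Mcm2, part of the replicative helicase, higher in DC at 26.0 against 5.03 FPKM and Tyms lower at 18.4 against 79.3. By the rule 1 gene was higher and 1 lower as deposited, 0 and 1 with median-ratio scaling, and 4 and 0 with equal sums. Immediate early and heat shock genes, which respond to tissue digestion, included Fos at 676, 1802 and 1589 FPKM in DC, macrophages and Gr-1+ CD11b+ cells and Dusp1 at 544, 2343 and 3380. Of these 20 genes, 2 were higher in macrophages than in DC by the rule (median -0.70, percentile 2.62; 1 with equal sums), 2 were higher in Gr-1+ CD11b+ cells than in DC (median -0.17 as deposited, 0.61 with median-ratio scaling), and 3 were lower than in macrophages (0 with median-ratio scaling). Of 7 phagocyte oxidase genes, Cybb was lower in Gr-1+ CD11b+ cells than in macrophages by the rule, at 37.4 against 313 FPKM. With median-ratio scaling 1 gene of this list was higher than in macrophages and 1 lower. Against DC, 1 was higher and 0 lower as deposited, and 0 and 1 with equal sums. Of 10 plasmacytoid dendritic cell genes, 1 was higher in DC than in macrophages by the rule (median 1.48, percentile 100), Ly6d at 1604 against 68.1, and 3 with equal sums. Of 9 mast cell and basophil genes and 5 glial and neuronal genes, 0 passed the rule in any comparison.

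All tests below were chosen after the results were seen, and the 3 patterns are hypotheses from single libraries. B and plasma cell genes stood out in the CD64- DC library. None of the 13 measured genes is in another list, and the most abundant, Jchain, reached 18847 FPKM. That all 13 passed the size rule against both other libraries is the pattern itself, so it does not test whether B or plasma cells were in the sorted population, and no gate against B cells is named in the labels. RNA shared freely at a similar level in the 3 libraries would not give a list median that differed by 4.16 between DC and macrophages. That value restates the same pattern, and free RNA at levels that differed between libraries was not tested. B or plasma cells in the sort, or a dendritic cell subset that uses these genes, may be the source, and the tables do not decide between them.

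Macrophage genes were present in the DC and Gr-1+ CD11b+ libraries at median shares of 11.4% and 10.9% of the macrophage level, with Apoe, their most abundant, at 2446 and 1657 FPKM against 19321; the CD64- gate should remove macrophages from DC, no such gate is named for Gr-1+ CD11b+ cells, and 2 of the 27 markers are in another list. For macrophages or their RNA carried over, the first of 3 tests per library went against it: the spread of the log2 shares was no narrower than in random matched lists (percentiles 50.6 and 63.4). The other tests were written after that result was seen: 6 and 9 of 27 markers lay more than 2-fold from the median share, against carry-over as the only source, and 0 and 0 of 27 fell below 50% of the lower-quartile share, as a floor of carried-over RNA would give, a form chosen with the shares in view. Of 70 abundant genes enriched in macrophages, 0 and 0 fell below that limit. Retnla, outside both sets, fell below it in Gr-1+ CD11b+ cells, at 53.4 against 1899 FPKM, so the floor did not hold for that gene. A single scale factor is argued against by housekeeping medians of 0.23 and -0.94 beside macrophage medians of -3.00 and -3.10. Carry-over stays an open hypothesis that may explain part of these values. Carry-over at 1 share for all genes could not exceed the lowest share of any gene. Among the markers that share was 7.72% in DC and 6.86% in Gr-1+ CD11b+ cells. Among the 70 enriched genes it was 5.21% and 4.85%, and Retnla set a lower limit still in Gr-1+ CD11b+ cells. At the lowest marker share carry-over would give 53.65% of P2rx4 in Gr-1+ CD11b+ cells and 21.34% in DC. At 1 share for all genes it would thus give less than this. The median share lies above these limits, may also hold the cells' own expression and can overstate carry-over. It would give 85.1% of P2rx4 in Gr-1+ CD11b+ cells (67.4% to 211% over the quartiles) and 31.4% in DC (27.3% to 61.3%). In DC it would give 24.45 of 23.65 FPKM of Adora2b, 4.20 of 4.29 of P2ry13 and 6.69 of 7.50 of P2ry6. In Gr-1+ CD11b+ cells it would give 23.4 of 29.5 FPKM of Adora2b.

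Genes of olfactory and vomeronasal receptors were above 0 in 594, 1220 and 1217 of 1452 cases in DC, macrophages and Gr-1+ CD11b+ cells. Lower depth spreads FPKM values and does not raise their mean, whereas the mean was 16.6 times higher, and the 10% trimmed mean 29.97 times higher, in Gr-1+ CD11b+ cells than in DC. Fragments from genomic DNA or from outside transcripts may be present: beta-defensin and keratin-associated protein genes stood in the same order of libraries, with a smallest step of 2.22-fold. No biological explanation was tested.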
